A study of Mus musculus with 2 samples.

How the data were processed

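The series holds single-nucleus RNA sequencing of the PVH of 17 mice, with 1 gene-expression library that pools all mice and 1 hashtag library without a file of its own. The authors deposited raw UMI counts per feature and barcode, with 31053 gene rows and 3 hashtag rows, per the file headers. Per the submitters' processing notes the counts came from Cell Ranger 6.0.0 on the mm10 build, while the matrix header names version 7.0.0. The counting annotation, the intron setting and the cell-calling settings are not given in the sources used here. Gene coordinates were taken from GENCODE vM21 on GRCm38, which held 30934 of the 31053 gene IDs. Library sizes were summed over gene rows alone.

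The plan, written before the data were examined, foresaw no comparison of genotypes, because no label links a hashtag to a genotype. It made an exception for a deposited file that maps barcodes to hashtags and hashtags to genotypes, but it also said that hashtag rows among the features would be described without a comparison. The deposited hashtag rows carry the names Ctrl, KD and Q153R. These names were taken as such a map and the pools were compared, a departure from the plan made after the names were seen. Ctrl and Q153R match genotypes in the labels, and KD is matched to the floxed genotype by elimination alone, so the pools are called nuclei labelled Ctrl, KD and Q153R. The lists, marker genes, rule for named genes and most alternative settings were fixed before the data were examined.

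Barcodes with at least 500 genes and under 5% mitochondrial UMIs were kept, which left 6157 of 6173. The highest mitochondrial share was 3.30%. Hashtag counts were fitted by a Gaussian mixture with 2 components on log10(count + 1) for each tag, and a tag was called at a posterior over 0.5. The background and positive means were 55.9 and 254 UMIs for Ctrl, 24.3 and 166 for KD, and 14.5 and 95.1 for Q153R. Of the barcodes, 1124 (18.3%) carried more than 1 tag, with a median of 11266.5 UMIs against 5252 for those with 1 tag, and 129 (2.10%) carried none. The planned doublet caller, Scrublet, marked 1 of 6157 nuclei (0.0162%) and was judged not to have worked. In its place all nuclei with more than 1 tag were removed. A further 583 nuclei, the number of within-pool doublets that the multiple-tag nuclei imply, were removed by the share of multiple-tag nuclei among their 50 nearest neighbours, which was at least 18% in each. The lowest share was close to the 18.3% among all barcodes that passed the filters, so removed nuclei near it need not be doublets. The doublet rule was chosen after the data were seen. It left 4450 nuclei with 23044516 UMIs, of which 4321 carried 1 tag.

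Counts were scaled to 10000 per nucleus and log-transformed. The 2000 most variable genes, with the 318 measured readout genes left out, gave 30 principal components, a graph of 15 neighbours and 19 Leiden clusters at resolution 1. Leading genes were the 10 with the highest fold over all other nuclei among genes with at least 20 UMIs, after adding 5 CPM. A cluster with at least 2 markers of 1 glial type among them was named after that type, and 1 with at least 2 GABAergic markers was called GABAergic-like. Of the rest, clusters with Sim1 at 200 CPM or more were called Sim1-expressing, and those with a single glial marker took that glial name. This rule was set after the clusters were seen, and the order of its steps was changed once after the alternatives had been run, which left the reported classes as they were. No cluster took a name from oligodendrocyte, endothelial, mural, ependymal, tanycyte or leptomeningeal markers.

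Levels are UMIs summed over nuclei and divided by summed library size, as CPM, with exact Poisson intervals. Shares have Clopper-Pearson intervals and ratios the exact conditional binomial interval, all at 95%. Ratios within clusters are Mantel-Haenszel ratios with Greenland-Robins intervals. For shares of nuclei with a UMI and for the comparisons by Otp or Mc4r UMIs, nuclei were thinned to 1998 UMIs, the 10th percentile, and shallower nuclei were left out. For Mc4r by pool, the share expected over all thinning draws was computed from the hypergeometric distribution, and odds ratios have exact conditional intervals. These values, and the count of nuclei with both Mc4r and Otp UMIs, were added after the other values were seen. For a share with a count of 0, the limit is that of 3 counts, while a ratio with a count of 0 keeps its exact interval. Pools were compared over summed UMIs of the Sim1-expressing clusters, which held 1399, 1006 and 1370 nuclei and 7705428, 5961708 and 6463067 UMIs in Ctrl, KD and Q153R.

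The 8 fixed readout lists covered energy-balance receptors, PVH transcription factors, neuropeptides, monogenic obesity genes, melanocortin signalling, activity genes, GABA and glutamate genes, and imprinted genes. Together with a technical list of sex-linked genes, they held 323 genes in all, some in more than 1 list. A list's median log2 ratio was placed among 10000 random lists of equal size matched on mean expression, as a description of these pools. Genes were named by a fixed rule. From the lists it took the 12 highest and 8 lowest ratios with at least 50 UMIs and an interval excluding 1. From all genes outside the variable set with at least 200 UMIs it took the 10 highest and 5 lowest. Across clusters it took the 5 members of each list with the largest ratio of the highest to the median cluster, among members with at least 100 UMIs. Mc4r, Otp, Sim1, Arnt2, Pou3f2, Lepr, Glp1r, Oxt, Avp, Crh, Trh and Sst were always given. Some genes that the rule takes are not reported here. Genes the text names beyond this rule were chosen after their values were seen. These are Gm48350, Gm48420, Tbca and Pde8b near Otp, Jun and Bdnf as exceptions in the activity list, Pcsk1 and Pcsk2 as exceptions in the neuropeptide list, Meis2 in Q153R, and Penk in cluster 0.

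The ratio step was tested on simulated counts with 200 genes changed. Counts were drawn from Poisson distributions, which the interval assumes, for genes with at least 200 UMIs. UMIs gathered in few nuclei or mice were not simulated. The coverage therefore checks the code and does not measure the error in these data. For KD to Ctrl over 8099 genes, the interval held the true ratio in 97.0% of genes at a fold of 0.5, 93.9% at 1 and 94.0% at 1.5. For Q153R to Ctrl over 8237 genes it did so in 94.0%, 94.2% and 94.0%. Settings listed beforehand changed the gene and mitochondrial limits, doublet removal, clustering resolution, principal components, variable genes, thinning, the UMI threshold, the averaging and the set of neurons. Added after the data were seen were Scrublet calls alone, multiple-tag removal alone, a hashtag posterior over 0.95, ratios within clusters, nuclei with at least 3 Xist UMIs and no Y-linked UMI, scaling to a median ratio of 1, and leaving out cluster 6. The analysis used Python 3.11.15, scanpy 1.11.5, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, igraph 0.11.9 and matplotlib 3.10.9.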

Results

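Nuclei were collected from the paraventricular hypothalamus (PVH), a region that controls appetite and pituitary hormone release, of 17 mice aged 4 weeks. All mice carried Sim1-Cre and a Sun1-GFP reporter, which places GFP on the nuclear envelope of cells that have expressed Cre, and GFP-positive nuclei were sorted. Of the mice, 7 had no Otp alteration, 4 carried a floxed Otp allele over a wild-type allele and 6 carried an Otp Q153R allele over a wild-type allele. Nuclei of all mice went into 1 droplet library of 6173 barcodes and 42833533 gene UMIs. The median barcode held 5681 UMIs, with a range of 508 to 61801, and 2477 genes. Hashtag antibodies marked the pools, and the deposited feature names call the tags Ctrl, KD and Q153R. The label KD is not spelled out, and by elimination it stands for the floxed genotype. After removal of nuclei called doublets 4450 nuclei were kept, of which 1742 were labelled Ctrl, 1133 KD and 1446 Q153R. The median nucleus held 5105.5, 5595 and 4439 UMIs in these pools. There was 1 pool per genotype, so no difference between pools has a replicate check and no p-value is given. All intervals are 95% intervals and cover counting error only.

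Most nuclei were neurons that expressed Sim1. Neurons made up 97.8% of kept nuclei (97.3–98.2) and fell into 16 clusters. Of these, 15 clusters expressed Sim1, a transcription factor needed for PVH development, and together held 87.1% of nuclei. The other neuron cluster was GABAergic-like, led by Gad1, Gad2, Slc32a1, Dlx1 and Dlx6os1, and held 475 nuclei or 10.7% (9.78–11.6). Sim1 stood at 17.1 CPM in it, against 353 to 1126 CPM in the others. Glial nuclei were few: 74 astrocyte-like, 15 oligodendrocyte-precursor-like and 9 microglia-like nuclei, together 2.2% (1.79–2.68). Their median of 1806 UMIs was below the neurons' 4970.5. An oligodendrocyte-like cluster appeared where nuclei removed as within-pool doublets were kept, which limits what the glial share can show.

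Several Sim1-expressing clusters stood out by the level of a peptide or transcription factor gene. Oxt, which encodes oxytocin, reached 9388 CPM in cluster 10, and Avp, which encodes vasopressin, 11889 CPM in cluster 15. Sst (somatostatin) reached 2368 CPM in cluster 3, Trh (thyrotropin-releasing hormone) 441 CPM in cluster 0, where Ucn3 stood at 334 CPM, and Crh (corticotropin-releasing hormone) 249.9 CPM in cluster 4. Cluster 12 held Oxt at 1300 CPM beside Esr2, which encodes oestrogen receptor beta. Bnc2 and Ebf2 marked cluster 7, and Nkx2-2 was highest in cluster 11 at 36.2 CPM. Among receptors of energy balance, Crhr2 was highest in cluster 2, Ramp1 in cluster 1, Adra1b in cluster 4, Oprk1 in cluster 10 and Ghr, the growth hormone receptor, in cluster 3 at 2089 CPM. Cluster 4, the largest with 743 nuclei, held the highest levels of 5 activity genes, Nptx2, Fosb, Arc, Nr4a3 and Nr4a1, the last at 202 CPM against a median cluster at 16.8 CPM. It was also highest for Gpr101, Pcsk1 and Ntrk2 among the obesity genes, whereas Sema3a was highest in cluster 10 and Bdnf in cluster 2. Of the melanocortin signalling list, Pde10a and Atrnl1 were highest in cluster 4, Adcy8 and Pde4b in cluster 15 and Kcnh7 in cluster 7. Among imprinted genes, Dlk1 and Peg10 led in cluster 4, Plagl1 in cluster 0, Nnat in cluster 1 and Snrpn in cluster 15. Slc17a6, the vesicular glutamate transporter of hypothalamic neurons, was highest in cluster 11 at 269 CPM. All readout genes were kept out of the clustering. Low Oxt and Avp levels in other clusters are not read as expression, since 26.9% of neurons and 29.5% of glia held an Oxt UMI at equal depth.

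The series asks for regulators of Mc4r, the melanocortin receptor whose loss causes obesity. Mc4r (chromosome 18, 66857704 to 66860506, minus strand, GRCm38) was scarce, with 69 UMIs over all neurons or 3.02 CPM. Its level was uneven: cluster 1, with Ppp1r17 among its leading genes, stood at 19.9 CPM (11.6–31.8), which was 8.4 times the other neurons (4.55–14.8). Cluster 12, led by Esr2, followed at 8.29 CPM (5.06–12.8), and 5 of 16 neuron clusters held no Mc4r UMI. Otp, a homeobox factor of PVH and neighbouring neuroendocrine neurons (chromosome 13, 94875602 to 94885130, plus strand), was spread more evenly. It was highest in cluster 5 at 140.2 CPM (123–159.5), 1.87 times the other neurons (1.62–2.15), and lowest in the GABAergic-like cluster at 2.03 CPM (0.660–4.75). Sim1 was highest in the Oxt cluster, Arnt2, its dimer partner, in cluster 4 at 808 CPM, and Pou3f2 in the Avp cluster at 229 CPM. The leptin receptor gene Lepr was highest in cluster 8 at 16.3 CPM and Glp1r in cluster 15 at 9.91 CPM.

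**Figure D1:**
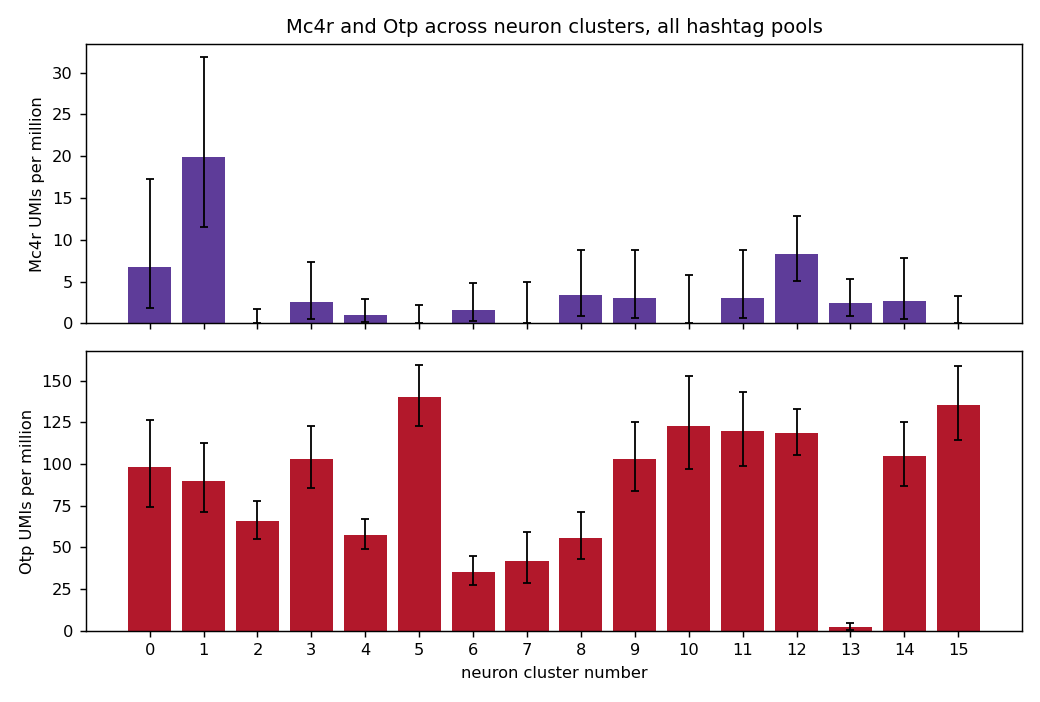
Bars give the summed CPM of Mc4r (top) and Otp (bottom) in each of the 16 neuron clusters, all pools together, with 95% Poisson intervals. Mc4r peaked at 19.9 CPM in cluster 1 and Otp at 140.2 CPM in cluster 5, while cluster 13 held Otp at 2.03 CPM.

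With every nucleus thinned to 1998 UMIs, Sim1 was detected in 51.4% of neurons (49.9–53.0), Otp in 13.2% (12.2–14.3) and Mc4r in 0.707% (0.470–1.02). Thinning left out 391 neurons. Without thinning the shares were 67.6%, 27.8% and 1.47%. In the GABAergic-like cluster, Sim1 was seen in 2.50% of thinned nuclei, Otp in 0.455% and Mc4r in 0.682%. Mc4r in that cluster was thus not distinguishable at this depth from the 0.710% in Sim1-expressing clusters. Of the 98 glial nuclei, unthinned, 0 held a Sim1 or Mc4r UMI, which allows a share of up to 3.06%, and 1 held an Otp UMI. At the glial median of 1806 UMIs this limits nuclei with a UMI, not nuclei that express the gene, and thinning left out 54 glial nuclei.

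Mc4r UMIs were compared between neurons with and without an Otp UMI, since the series asks which factors go with Mc4r. Neurons with an Otp UMI held Mc4r at 2.09 times the level of those without (0.753–5.06), from 7 and 22 Mc4r UMIs, and 1.90 times within clusters (0.782–4.61). Both intervals include 1, so a difference was not detectable at this depth. The ratio was 0.767 (0.340–1.70) for Sim1 and 1.47 (0.656–3.26) for Arnt2. Neurons with a Pou3f2 UMI held 0 of the 29 Mc4r UMIs, a ratio whose interval reached 1.74. These are co-detections in 1 library.

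Read the other way, the 28 thinned neurons with an Mc4r UMI were set against the other neurons gene by gene. Drd2, a dopamine receptor, was at 7.14 times the level of other neurons (1.43–21.9), Npy1r, a neuropeptide Y receptor, at 6.53 times (2.35–14.6), and Ghr at 2.50 times (1.90–3.23), or 1.60 within clusters (1.24–2.06). The factors Nfix (6.38), St18 (5.54) and Nfib (2.91) were higher, and so were the imprinted obesity gene Magel2 at 2.40 times and Adcy9 at 2.53 times. These intervals count the UMIs of 1 nucleus as independent. In the nuclei with an Mc4r UMI, Drd2, Nfix and St18 each rested on 3 UMIs and Npy1r on 6. Otp stood at 2.49 times (1.24–4.48), or 2.25 within clusters (1.23–4.13), but its 11 UMIs lay in 7 of the 28 nuclei. Counted by nuclei, the odds ratio of holding an Otp UMI was 2.20 (0.787–5.41), so the difference was not detectable, as in the split by Otp. Within clusters Npy1r stood at 3.82 (1.70–8.59), while Nfix, at 1.92 (0.585–6.28), and Nfib, at 1.56 (0.922–2.63), had intervals that included 1. Hcrtr2 (2.23) and Thrb (1.98) were also higher, but within clusters Hcrtr2 stood at 1.56 (0.830–2.94) and Thrb at 1.01 (0.686–1.48). Lower were Ebf1 (0.180), Snrpn (0.183), Htr2c (0.220), Klf12 (0.556), Sim1 (0.611, 0.349–0.993), Hdac9 (0.625), Zfhx3 (0.644) and Avp (0.339). Within clusters the intervals of 5 of these included 1, with Ebf1 at 0.445 (0.111–1.78), Klf12 at 0.833 (0.508–1.36), Sim1 at 0.615 (0.375–1.01), Zfhx3 at 0.914 (0.611–1.37) and Avp at 1.58 (0.918–2.70). Over the lists, the median log2 ratio was 0.45 for receptors, at the 97th percentile of 10000 random lists matched on expression, whose median was 0.29, and 0.01 for transcription factors, at the 13.8th with a random median of 0.09, or 0.18 without the cluster with the highest Mc4r level. It was 0.16 for neuropeptides (50.9th, random 0.16), 0.14 for obesity genes (63.4th, random 0.07) and 0.05 for melanocortin signalling (54.2th, random 0.03). Activity genes stood at −0.04 (26.2th, random 0.20), GABA and glutamate genes at −0.05 (28.0th, random 0.22) and imprinted genes at −0.03 (42.6th, random −0.01). These values rest on 28 nuclei, of which 9 lay in cluster 1 and 6 in cluster 12. The ranking beyond the lists took genes with at least 200 UMIs outside the variable set. Of these, 3632451O06Rik (5.62), Ssx2ip (4.30), Fbn1 (4.11) and Nob1 (4.01) were among those with the highest ratios. They rested on 8, 6, 7 and 7 UMIs in the nuclei with an Mc4r UMI. They are the extremes of a ranking of many genes, and no allowance was made for the number ranked.

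Otp, the altered gene, was higher in the nuclei labelled KD and Q153R than in those labelled Ctrl. In the Sim1-expressing clusters it stood at 58.7 CPM in nuclei labelled Ctrl (53.4–64.3), 91.8 CPM in nuclei labelled KD (84.2–99.8) and 123.5 CPM in nuclei labelled Q153R (115–132). The ratio to Ctrl was 1.56 for KD (1.38–1.78) and 2.10 for Q153R (1.87–2.37), and Q153R exceeded KD 1.35 times (1.21–1.5). Otp was higher than in Ctrl in 13 of 15 clusters for KD and in 14 of 15 for Q153R, where cluster 4 reached 4.09 times. At equal depth, 10.1%, 14.3% and 20.3% of nuclei held an Otp UMI. The direction goes against the label KD read as a knockdown of Otp. The floxed exons are not given in the sources used here and the UMIs tag transcript 3′ ends. Otp UMIs therefore do not measure intact transcript and do not check the labels.

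Wdr41, the next gene downstream of Otp on the same strand, had the largest KD ratio among genes with at least 200 UMIs outside the variable set. It lies on chromosome 13 from 94976344 to 95023314, beginning 91214 bp past the end of Otp. Wdr41 stood at 49.7 CPM in Ctrl, 288 CPM in KD and 79.7 CPM in Q153R, a ratio of 5.79 for KD (5.18–6.48) and 1.60 for Q153R (1.40–1.83). It was higher in KD than in Ctrl in 15 of 15 Sim1-expressing clusters, by 2.95 to 13.2 times. In the GABAergic-like cluster, where Otp was at 2.03 CPM, the KD ratio was 0.959 (0.571–1.56) and the Q153R ratio 1.23 (0.637–2.2). Other genes of the interval were looked up after these values were seen. Gm48350, antisense to Wdr41, had a KD ratio of 2.75 (1.66–4.67) and Gm48420, next to its end, 3.48 (2.19–5.69). Both are uncertain, since the counting is not stated to use strand. Tbca upstream of Otp and Pde8b beyond Wdr41 were each at 1.14.

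**Figure D2:**
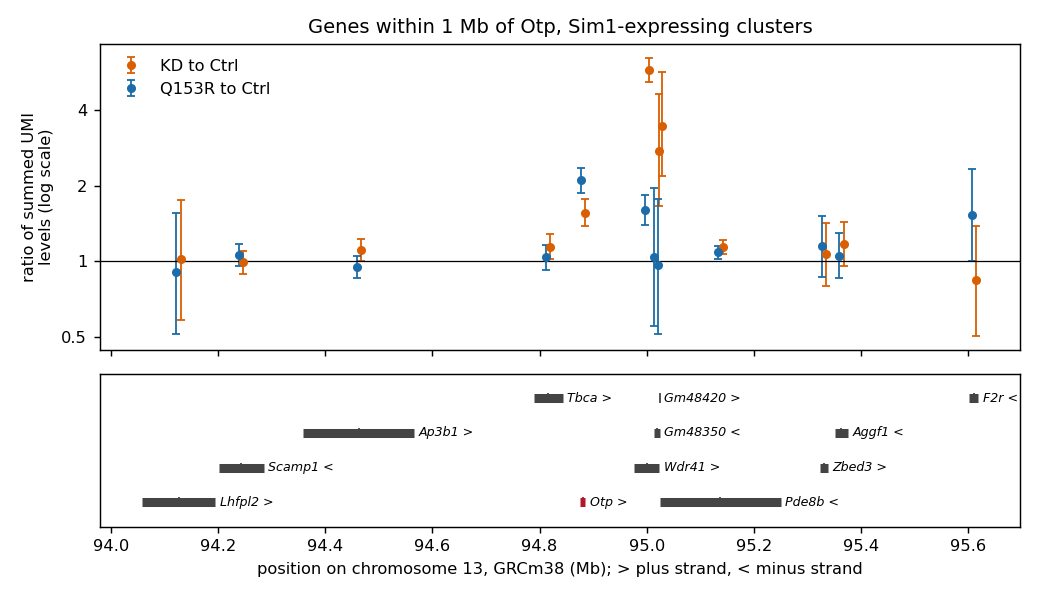
Upper panel, ratio of summed UMI levels to the Ctrl pool (log scale, 95% intervals) in the Sim1-expressing clusters for genes within 1 Mb of Otp with at least 50 UMIs, at gene midpoints set slightly apart for KD and Q153R; lower panel, gene positions on chromosome 13 in Mb. Wdr41 stands at 5.79 for KD and Otp at 1.56 for KD and 2.10 for Q153R.

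**Figure D3:**
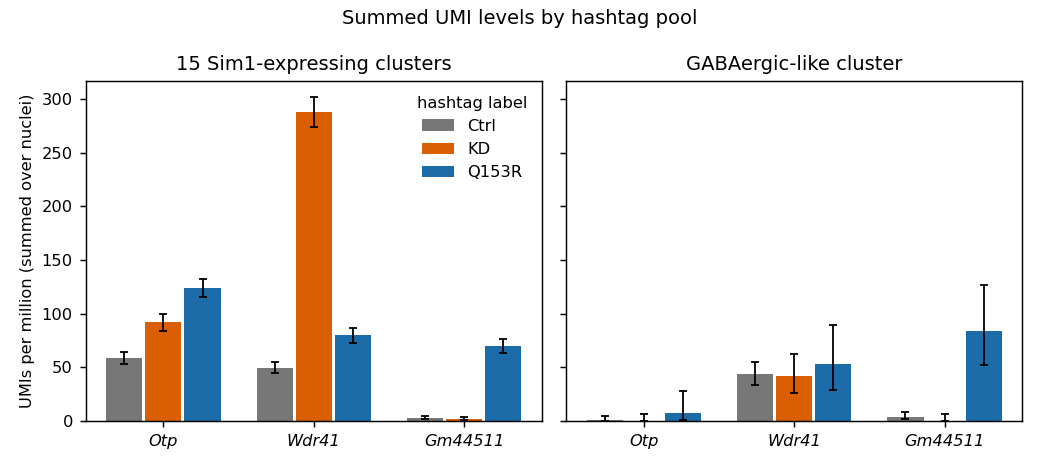
Bars give the summed CPM of Otp, Wdr41 and Gm44511 by hashtag label, with 95% Poisson intervals, in the Sim1-expressing clusters (left) and the GABAergic-like cluster (right). Wdr41 in KD reaches 288 CPM on the left and 41.6 CPM on the right, and Gm44511 in Q153R 69.9 and 83.5 CPM.

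The pools differed in their classes of nuclei, which the design text names as a question. The GABAergic-like cluster held 17.2% of Ctrl nuclei (15.5–19.1), 8.91% of KD nuclei (7.32–10.7) and 4.29% of Q153R nuclei (3.30–5.46). Against Ctrl, the odds ratio was 0.471 for KD (0.367–0.600) and 0.215 for Q153R (0.160–0.287), which was 0.455 at a clustering resolution of 0.5. Glial clusters held 2.47%, 2.29% and 0.968%, an odds ratio of 0.928 for KD (0.544–1.56) and 0.386 for Q153R (0.194–0.724). Sim1-expressing clusters made up the complement of 80.3%, 88.8% and 94.7%. Among their nuclei, cluster 2, led by Qrfpr and Crhr2, took 6.93% in Q153R against 10.8% in Ctrl, a ratio of 0.642 (0.492–0.836). Cluster 8, led by 4930509J09Rik, took 5.96% in KD against 3.93% in Ctrl, a ratio of 1.52 (1.03–2.23). Share ratios to Ctrl were computed for 15 clusters in both KD and Q153R, and the intervals of all others included 1. No allowance was made for their number. The sort for GFP and the dissection can set such shares. The doublet rule removed 11.4% of Ctrl, 15.9% of KD and 9.11% of Q153R nuclei that carried 1 tag.

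**Figure D4:**
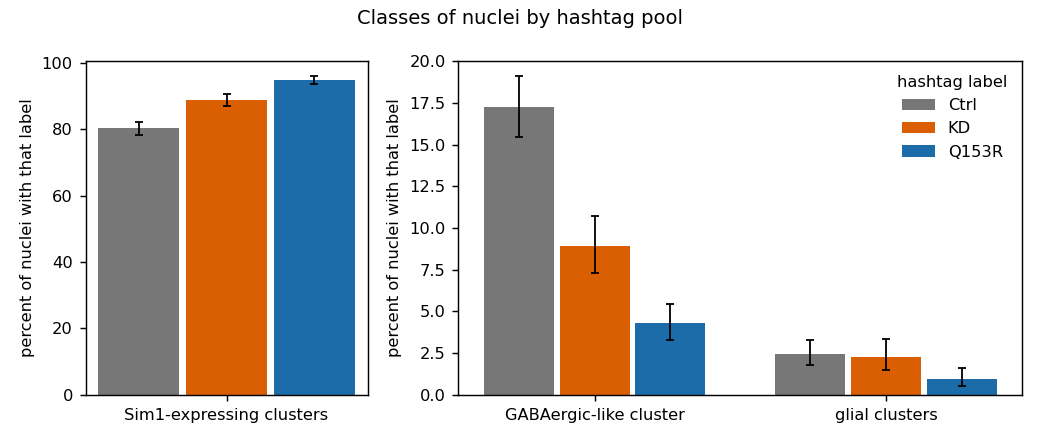
Bars give the percent of nuclei with each hashtag label that fell in the Sim1-expressing, GABAergic-like and glial clusters, with 95% binomial intervals. The GABAergic-like share is 17.2% in Ctrl, 8.91% in KD and 4.29% in Q153R.

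The mix of sexes also differed between pools. Nuclei with at least 3 UMIs of Xist, which is expressed from the inactive X chromosome, and no Y-linked UMI made up 65.5% of Ctrl (63.2–67.7), 82.5% of KD (80.2–84.7) and 48.3% of Q153R (45.7–51.0). Nuclei with at least 2 Y-linked UMIs made up 14.1%, 1.41% and 26.6%. For named genes whose interval excluded 1, the ratio within clusters or in the Xist nuclei is given where its interval included 1, or where it moved by over 1.5 times or crossed 1. For list medians below, the random lists had medians from −0.05 to 0.02.

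Nuclei labelled KD held lower levels of several hypothalamic peptides than nuclei labelled Ctrl. Trh was at 0.555 times the Ctrl level (0.478–0.643), Ucn3, which encodes urocortin 3, at 0.486 (0.320–0.725), Crh at 0.688 (0.578–0.817) and Sst at 0.706 (0.651–0.766). In the Xist nuclei Ucn3 was at 0.696 (0.433–1.10). Within their own clusters Trh went from 596 to 260.1 CPM, Ucn3 from 434 to 217 CPM, Crh from 287 to 215 CPM and Sst from 2563 to 2043 CPM. Over the neuropeptide list, 10 of 28 measured members lay above 1 and the median log2 ratio was −0.21, at the 0.0100th percentile of matched random lists. Oxt was at 0.790 (0.756–0.826) and 0.946 within clusters. In its own cluster, however, Oxt was higher in KD, going from 9805 to 11072 CPM, a ratio of 1.13 (1.06–1.20). Avp was at 1.19 (1.15–1.24) but 0.995 within clusters. Pmch, which encodes melanin-concentrating hormone, was at 6.55 times, yet 66 of its 76 UMIs came from 1 nucleus, and without cluster 6 the ratio was 0.976.

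Transcription factors differed in both directions between KD and Ctrl. Bcl11b was at 2.88 times (1.96–4.29), Bnc2 at 1.82 (1.43–2.31), Ebf2 at 1.71 (1.47–1.99), Lhx2 at 1.69, Etv5 at 1.48 and Ebf3 at 1.34. With 4000 variable genes Bnc2 was at 1.15. Meis2, at 1.82 (1.08–3.10), came from 38 UMIs in 15 nuclei, lay below 1 under 3 alternative settings and at 3.95 under another, and stood at 1.53 (0.875–2.70) in the Xist nuclei. Lower were Sox6 at 0.298 (0.145–0.566), St18 at 0.366 (0.191–0.659), Nfia at 0.506 (0.424–0.600) and Nhlh2 at 0.579. In the Xist nuclei St18 was at 0.627 (0.292–1.29), and Sox6 ranged from 0.159 to 0.476 over the alternatives. Sox6 led the oligodendrocyte-precursor-like cluster, and St18 and Meis2 were leading genes of the GABAergic-like cluster, which held 8.91% of KD nuclei against 17.2% of Ctrl. The list as a whole had 39 of 74 members above 1, with a median log2 ratio of 0.02 at the 96.9th percentile. Sim1 stood at 0.958 (0.914–1.0), Arnt2 at 1.05 and Pou3f2 at 1.03, each with an interval that included 1.

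Mc4r was at 2.18 CPM in KD and 3.50 CPM in Ctrl, from 13 and 27 UMIs, a ratio of 0.622 (0.295–1.25) whose interval included 1. Among thinned nuclei, 2 of 942 in KD and 13 of 1282 in Ctrl held an Mc4r UMI, or 0.212% (0.0257–0.765) and 1.01% (0.541–1.73), an odds ratio of 0.208 (0.0227–0.921). Thinning is a random draw, and over all draws the expected shares were 0.446% and 0.664%. Without thinning, the shares were 1.09% and 1.86%, with an odds ratio of 0.584 (0.259–1.23). A lower Mc4r level in KD is thus neither shown nor excluded at this depth. Sstr1, a somatostatin receptor, was at 1.89 times (1.12–3.24), Glp1r at 2.84 times (1.29–6.73, from 22 and 10 UMIs) and Lepr at 0.595 (0.369–0.938), but in the Xist nuclei Sstr1 was at 1.75 (0.954–3.29) and Lepr at 0.924 (0.521–1.63). Receptors had a median log2 ratio of 0.00 (85.9th percentile), obesity genes −0.02 (64.5th), melanocortin signalling −0.01 (60.3th) and GABA and glutamate genes 0.00 (66.1th). Imprinted genes stood at −0.08 (0.485th), with 5 of 20 members above 1. Activity genes had a median of 0.02 (78.5th), although Nr4a3 was at 1.69 (1.35–2.12) and Fos at 1.33 (1.0–1.77). In the GABAergic-like cluster Nr4a3 was also higher in KD, at 2.92 (1.40–6.08), and Fos was at 1.80 (0.645–4.67). Outside the lists, Gm16124 (1.92), Prkg2 (1.57), Wnt5b (1.55), Gm43154 (1.55) and Mknk1 (1.55) were higher. The chaperone genes Hsph1 (0.544, 0.455–0.649) and Cct7 (0.579) and the sterol synthesis gene Hmgcs1 (0.570) were lower. Hsph1 was also lower in the GABAergic-like cluster, at 0.564 (0.314–0.955), so its difference was not limited to the Sim1-expressing clusters. Ratios over 8099 genes had a log2 SD of 0.19 around a median of −0.04.

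In nuclei labelled Q153R, genes induced by neuronal activity were higher than in nuclei labelled Ctrl. Nr4a3 was at 2.50 times (2.04–3.08), Arc at 1.96 (1.29–2.99), Fos at 1.91 (1.48–2.47), Fosl2 at 1.74 (1.45–2.09), Egr1 at 1.68 (1.24–2.28), Fosb at 1.55 (1.09–2.21) and Npas4 at 1.49 (1.26–1.76), or 1.18 in the Xist nuclei (0.951–1.46). Of the 14 measured activity genes, 12 lay above 1. Jun, at 0.840 (0.637–1.10), and Bdnf, at 0.907 (0.766–1.07), were the exceptions. The list's median log2 ratio of 0.49 was at the 100th percentile of matched random lists, and it was 0.33 in the Xist nuclei. Random lists were matched on level alone, whereas several activity genes were highest in the same cluster and may move together. Percentiles of this list, in any comparison of pools, therefore do not measure how often such a shared shift arises. Counts in the GABAergic-like cluster were few, with Fos at 0.943 (0.103–4.16) from 2 and 13 UMIs and Nr4a3 at 2.52 (0.885–6.40).

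**Figure D5:**
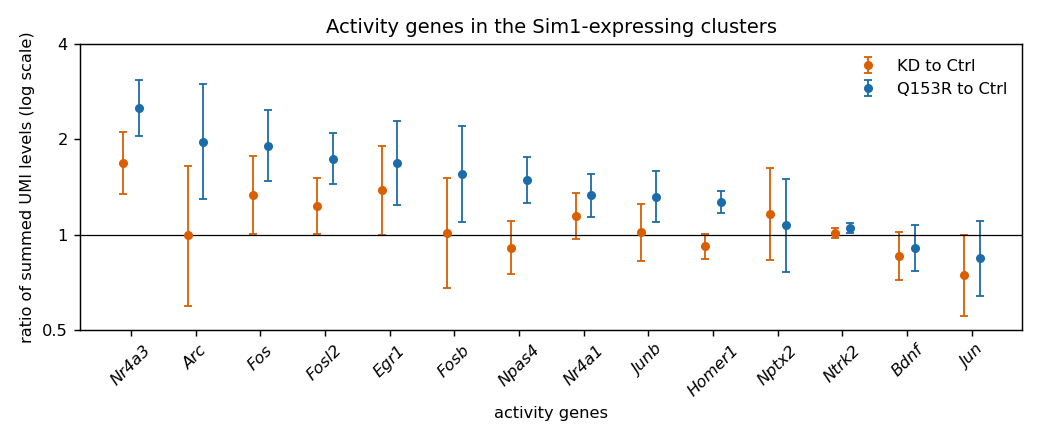
Points give the ratio of summed UMI levels (log scale) of each activity gene to the Ctrl pool in the Sim1-expressing clusters, for KD and Q153R, with 95% intervals. In Q153R 12 of 14 genes lie above 1, with Nr4a3 at 2.50, and in KD Nr4a3 is at 1.69.

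Some peptide genes were lower in the Q153R pool than in Ctrl. Oxt was at 0.740 times Ctrl (0.708–0.773) and Sst at 0.806 (0.747–0.869), but Sst was at 0.931 within clusters, with an interval that included 1 (0.864–1.0). In its own cluster Oxt went from 9805 to 7625 CPM, a ratio of 0.778 (0.731–0.827). Crh, at 0.949 (0.814–1.10), and Trh, at 0.893 (0.789–1.01), had intervals that included 1. Trh was lower within clusters, however, at 0.867 (0.767–0.981), and in its own cluster, at 0.725 (0.553–0.9496). Intervals still included 1 for Trh in the Xist nuclei, at 0.856 (0.721–1.01), and for Crh in its own cluster, at 0.853 (0.717–1.01). Avp was at 0.919 (0.885–0.955) and at 1.02 in the Xist nuclei (0.976–1.07). Over all Q153R nuclei of its own cluster, Avp was lower than in Ctrl, at 0.862 (0.825–0.9001). Of the list's peptide-processing enzymes, Pcsk1 was at 1.27 (1.17–1.37) and Pcsk2 at 1.08 (1.04–1.12). The neuropeptide list had 8 of 26 members above 1 and a median log2 ratio of −0.14, at the 0.0400th percentile.

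Transcription factors leaned higher in Q153R, with 48 of 77 members above 1 and a median log2 ratio of 0.06 at the 99.99th percentile. Bcl11b was at 2.15 (1.44–3.24) and Zic2 at 1.61 (1.09–2.37). In the Xist nuclei Bcl11b was at 1.21 (0.668–2.14) and Zic2 at 1.14 (0.668–1.92). Lower were St18 at 0.427 (0.239–0.734), Sim2 at 0.495 (0.317–0.757), Nfia at 0.602 (0.513–0.705) and Nfib at 0.650 (0.572–0.738). In the Xist nuclei St18 was at 0.763 (0.324–1.67), Nfia at 0.877 (0.703–1.09) and Nfib at 0.859 (0.723–1.02). St18 was a leading gene of the GABAergic-like cluster, which held 4.29% of Q153R nuclei against 17.2% of Ctrl, and so was Meis2, at 0.0883 (0.0102–0.351) from 2 and 27 UMIs. Sim2, a leading gene of cluster 2, whose share was lower in Q153R, was at 0.666 within clusters (0.441–1.01). Sim1 was at 1.07 (1.02–1.12), Arnt2 at 1.08, or 1.05 in the Xist nuclei (0.973–1.14), and Pou3f2 at 0.964 (0.828–1.12).

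Mc4r was at 3.56 CPM in Q153R, a ratio to Ctrl of 1.02 (0.556–1.84) from 23 and 27 UMIs, so a difference was not detectable at this depth. Of thinned Q153R nuclei 0.794% held an Mc4r UMI (0.381–1.45), against 0.781% expected over all draws. In the Xist nuclei the ratio was 1.66 (0.803–3.41). In cluster 1, where Mc4r was highest, it stood at 20.6 CPM in Ctrl (8.27–42.4), 21.0 in KD (5.71–53.7) and 18.9 in Q153R (6.92–41.0). These levels rest on 7, 4 and 6 UMIs, so a change in this cluster is neither shown nor excluded. Irs2, which encodes an insulin receptor substrate, was at 1.51 (1.29–1.78). Nmur2 (0.596), Ramp1 (0.657) and Trhr (0.700) were lower, but Nmur2 at 0.621 (0.335–1.10) and Ramp1 at 0.782 (0.516–1.17) in the Xist nuclei, and Trhr at 0.788 (0.602–1.03) within clusters, had intervals that included 1. Lepr was at 0.814 (0.539–1.22), with 1.29 in the Xist nuclei, and Glp1r at 0.596 (0.160–1.91), with 0.292 in the Xist nuclei. Receptors had a median log2 ratio of 0.02 (90th percentile), obesity genes 0.05 (98.9th), melanocortin signalling 0.01 (66.6th), GABA and glutamate genes −0.03 (43.4th) and imprinted genes 0.00 (53.9th).

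Gm44511, on chromosome 6 from 128780285 to 128826315, had the highest Q153R ratio among genes with at least 200 UMIs outside the variable set. It rested on 452 UMIs in Q153R against 22 in Ctrl and 12 in KD, a ratio to Ctrl of 24.5 (16.0–39.5), and in the GABAergic-like cluster of 22.5 (8.84–67.7). On the same chromosome, Gt(ROSA)26Sor (113067428 to 113077333) was at 1.92 (1.52–2.45) and Pzp at 0.635 (0.519–0.775). Cdc42ep3 (1.90), Mknk1 (1.70) and Gm15446 (1.61, but 1.35 in the Xist nuclei, 0.986–1.83) were also higher. The sterol-related gene Acat2 (0.564), A830019P07Rik (0.574) and Utp6 (0.615) were lower. Over 8237 genes the log2 SD was 0.18 around a median of −0.02.

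Set against nuclei labelled KD, nuclei labelled Q153R held higher levels of some peptides. Ucn3 was at 2.69 times (1.81–4.07, 1.71 within clusters and 4.16 with at least 1000 genes), Penk, an opioid peptide precursor, at 1.68 (1.39–2.03), Trh at 1.61 (1.38–1.88) and Crh at 1.38 (1.15–1.65). Avp (0.770, 0.740–0.800) was lower, and so was Oxt at 0.936, which was 1.08 in the Xist nuclei. Pmch was at 0.0850, but 66 of its 76 UMIs in KD came from 1 nucleus, and the ratio reached 0.783 under alternatives. Sst was at 1.14, or 1.09 in the Xist nuclei (0.983–1.22). The neuropeptide list had a median log2 ratio of 0.01 (57.2th percentile). Activity genes stood at 0.42 (100th), with 13 of 14 members above 1, Arc at 1.97, or 1.69 in the Xist nuclei (0.979–2.94), and Npas4 at 1.64. Imprinted genes stood at 0.11 (99.9th), with Peg10 at 1.83 (1.63–2.06), and obesity genes at 0.09 (99.1th), although Ndn was at 0.717.

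Among factors and receptors in the same comparison, Sox6 (3.15), Prdm16 (1.84), Nhlh2 (1.63), Npy5r (1.74) and Calcr (1.62, 1.46–1.80) were higher in Q153R. Sox6 ranged from 1.99 to 5.46 over the alternatives, and Npy5r was at 1.61 within clusters (0.994–2.61) and 1.74 in the Xist nuclei (0.906–3.36). Bnc2 (0.501), Ebf2 (0.607), Ptger3 (0.548) and Etv5 (0.756) were lower. Bnc2, with UMIs in 23 KD and 24 Q153R nuclei, was at 0.709 within clusters (0.552–0.911) and at 0.851 with 4000 variable genes. Tcf7l2 was at 0.488 (0.294–0.793), at 1.53 without cluster 6 and at 0.733 in the Xist nuclei (0.402–1.29). Transcription factors as a list had a median log2 ratio of 0.04 (90.5th percentile), receptors 0.04 (81.3th), melanocortin signalling 0.00 (47.4th) and GABA and glutamate genes −0.03 (31.4th). Mc4r was at 1.63 (0.793–3.51) from 23 and 13 UMIs. In the Xist nuclei alone Mc4r was at 2.69 (1.16–6.57), an interval that excluded 1. That subset was chosen after the data were seen and holds fewer UMIs, and no allowance was made for the number of ratios computed in it. Against Ctrl, Mc4r in the Xist nuclei was at 0.616 (0.254–1.41) in KD and 1.66 (0.803–3.41) in Q153R, intervals that included 1. Lepr was at 1.37 (0.835–2.27) and Glp1r at 0.210 (0.0620–0.567, from 5 and 22 UMIs, and 0.0753 in the Xist nuclei). Sim1 was at 1.12, Arnt2 at 1.02 and Pou3f2 at 0.940. Outside the lists, Hsph1 (2.15), Slc5a3 (1.78), Cacybp (1.76), Hist1h2be (1.69), P4ha2 (1.67) and Adamts16 (1.67, but 1.14 in the Xist nuclei, 0.769–1.69) were higher, and Wdr41 (0.277), Gm11817 (0.613) and Cfap54 (0.620) lower.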

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

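The tests of population mix, sex mix, exchanged tags, sorting and doublet calls were chosen after the results were seen, while those on chromosome 6 were set before.

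Otp UMIs were higher in the nuclei labelled KD and Q153R than in those labelled Ctrl. Another mix of neuron populations is argued against as the whole cause, since the lowest lower bound of the ratio within clusters was 1.36 over both labels. Another mix of sexes is argued against in the same way, with a lowest lower bound of 1.37 in nuclei with Xist and no Y-linked UMI. An exchange of the Ctrl and KD tags cannot be told apart from a change of Otp: Otp UMIs do not measure intact transcript and so do not decide, and Wdr41, at 5.79 times in KD, speaks against it only if a raised Wdr41 marks the floxed allele. An effect of the altered alleles on Otp transcription or on the stability of its mRNA was not tested and stays open.

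The GABAergic-like cluster took a smaller share of the Q153R nuclei than of the Ctrl nuclei. Loss to the within-pool doublet calls is argued against as the whole cause. With no doublet removed, the odds ratio among nuclei with 1 tag was 0.251 (0.195–0.320). Nuclei with more than 1 tag have no single label and were not counted in it, so their loss could not be tested. A tighter sort or dissection may contribute, since glial nuclei had an odds ratio of 0.386 (0.194–0.724), whose interval includes the 0.215 of the GABAergic-like cluster. In KD, however, the glial odds ratio of 0.928 (0.544–1.56) had an interval above the 0.471 of the GABAergic-like cluster. A loss of these neurons with altered Otp was not tested and stays open.

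Gm44511 and Gt(ROSA)26Sor, 15702952 bp apart on chromosome 6, were both higher in the Q153R nuclei. A change that comes with altered Otp is argued against for Gm44511, since its ratio in the GABAergic-like cluster, where Otp is hardly expressed, was 22.5 (8.84–67.7). A linked chromosome 6 haplotype that differs between the pools may contribute: 155 genes between and around them had a median absolute log2 ratio of 0.18 against 0.14 in matched random lists, at their 98.9th percentile, a small excess beside the ratio of 24.5 for Gm44511. Gt(ROSA)26Sor was also higher in the GABAergic-like cluster, at 4.98 times (2.2–11.0). No variant was called in these data, and the strains and the position of the reporter transgene are not given in the sources used here.

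Some genes lay on opposite sides of 1 in the KD and Q153R pools, each against Ctrl, and these differences were not tested. Only named genes were searched. Of these, Peg10, Calcr, Slc5a3, Cacybp and Cfap54 were named for their Q153R to KD ratio alone, which makes opposite sides more likely. Meis2 was at 1.82 in KD and 0.0883 in Q153R, from 38 UMIs in 15 KD nuclei and 2 UMIs in Q153R. The KD value of Meis2 lay at 0.832, 0.981 and 0.994 under 3 alternatives and its interval in the Xist nuclei included 1 (0.875–2.70). Meis2 was a leading gene of the GABAergic-like cluster, which held 17.2% of Ctrl, 8.91% of KD and 4.29% of Q153R nuclei. Hsph1 was at 0.544 and 1.17, Peg10 at 0.789 and 1.44, and Calcr at 0.762 and 1.23. Slc5a3 stood at 0.809 and 1.44, Cacybp at 0.710 and 1.25, and Cfap54 at 1.21 and 0.750. The Q153R intervals of Hsph1 (1.02–1.34) and Cacybp (1.02–1.54) had lower bounds close to 1. Hsph1 encodes a heat shock protein, Peg10 is an imprinted gene and Calcr encodes the calcitonin receptor.

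Nuclei with more than 1 hashtag, which no comparison used, made up 18.3% of the barcodes that passed the filters.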

How the results depend on the processing

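The alternatives on hashtags, within-cluster ratios, Xist nuclei, scaling and cluster 6, and those that removed Scrublet calls or multiple-tag nuclei alone, were chosen after the results were seen. Over 136 results and 2014 alternative values, 1878 stayed within their counting interval or, for the number of neuron clusters, which ranged from 13 to 26, within 1.5 times; 122 moved beyond that and 14, called on 1 side of a ratio of 1 as reported, crossed to the other side. The KD to Ctrl ratio ranged from 1.52 to 1.61 for Otp and from 5.58 to 6.05 for Wdr41, and the Q153R to Ctrl ratio of Otp from 2.03 to 2.50. The Mc4r ratio ranged from 0.539 to 0.660 for KD and from 0.881 to 1.66 for Q153R, from 13 and 27 UMIs and 23 and 27 UMIs as reported, which leaves wide intervals. The ratio of Mc4r by Otp ranged from 1.02 to 2.74. No paired analysis was possible because each genotype is 1 pool.

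The following values moved, and except for the thinning and UMI settings, whose construction sets the share, the cause was not tested. With at least 1000 genes, neurons made up 99.6%, Sim1, Otp and Mc4r were detected in 58.5%, 17.2% and 1.04% of them, and the highest Otp cluster stood at 161 CPM. With no doublet removal neurons made up 95.1%, with Sim1 in 55.3% and Otp in 15.8%. With Scrublet calls alone removed the values were 95.2%, 55.1% and 15.7%, with Trh at 383 CPM in its highest cluster. With multiple-tag nuclei alone removed neurons made up 96.2%, and Meis2 KD to Ctrl crossed to 0.981. At a hashtag posterior over 0.95 neurons made up 97.2%, Otp was in 14.7%, Meis2 was at 0.994 and Tcf7l2 Q153R to KD crossed to 1.53. At resolution 0.5 the GABAergic-like odds ratio was 0.455, Pmch KD to Ctrl crossed to 0.967 and Tcf7l2 to 1.52, and resolution 2 gave 26 neuron clusters. With readout genes allowed in the clustering, Pmch was at 0.864 and Meis2 at 0.832. With 50 principal components neurons made up 99.1%, Otp was in 14.7% and Pmch was at 0.844. With 4000 variable genes neurons made up 94.1%, the highest Otp cluster stood at 159.6 CPM and Pmch was at 0.959. Without cluster 6, Pmch was at 0.976 and Tcf7l2 at 1.53.

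Sim1, Otp and Mc4r were detected in 67.6%, 27.8% and 1.47% without thinning, 72.9%, 27.3% and 1.22% at the median depth, and 24.6%, 2.22% and 0.0252% at 2 or more UMIs. Without the cluster with the highest Mc4r level, the median log2 ratio of transcription factors by Mc4r was 0.18. Within clusters Avp KD to Ctrl was 0.995. In the Xist nuclei Otp Q153R to Ctrl was 2.50, the activity median log2 ratio 0.33, Avp Q153R to Ctrl 1.02 and Oxt Q153R to KD 1.08. Scaling to a median ratio of 1 gave receptors a KD to Ctrl median log2 ratio of 0.0484.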

Other observations

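The test on a linked variant and the test on transcription past Otp were both set before their result was seen. The values by pool in single clusters were chosen after they were seen.

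Cluster 0, the small population with Ucn3, Trh and Penk, held peptide genes at different levels in the pools. Penk stood at 486 CPM in Ctrl (392–595), 36.1 CPM in KD (11.7–84.3) and 276 CPM in Q153R (216–348). The ratio to Ctrl was 0.0744 in KD (0.0236–0.180) and 0.568 in Q153R (0.411–0.782), from 93, 5 and 71 UMIs. Ucn3 stood at 434, 217 and 327 CPM and Trh at 596, 260.1 and 432 CPM in the same order. The cluster held 33 Ctrl, 20 KD and 47 Q153R nuclei, so a few nuclei weigh on each value. Trh was higher in KD than in Ctrl in 3 of 15 Sim1-expressing clusters, at most 2.06 times (0.107–122) in cluster 15, from 2 and 1 UMIs. Outside cluster 0, the clusters whose interval excluded 1 were all lower in KD, at 0.559 (0.428–0.723) in cluster 2, 0.458 (0.238–0.830) in cluster 5 and 0.163 (0.0504–0.409) in cluster 9. In cluster 1, where Mc4r was highest, it was at 1.29 (0.919–1.81).

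The ratio of Otp to Ctrl varied over the Sim1-expressing clusters. In the Q153R pool it was highest in cluster 4, which holds Crh and the highest activity gene levels, at 4.09 (2.69–6.40), and lowest in cluster 7 at 0.737 (0.224–2.17). In KD it was highest in cluster 11, where Nkx2-2 was highest, at 3.16 (1.80–5.83), and lowest in cluster 0 at 0.922 (0.405–2.02). In cluster 1, where Mc4r was highest, the ratio was 3.06 (1.67–5.94) in Q153R and 2.26 (1.09–4.78) in KD. Differences between clusters were not tested.

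A hypothesis for Wdr41 is that transcription from the altered Otp allele runs on into it, since it lies next downstream on the same strand. Such a cause needs Otp transcription, and in the GABAergic-like cluster, where Otp is hardly expressed, the Wdr41 ratio of KD to Ctrl was 0.959, against 5.79 in the Sim1-expressing clusters, which is consistent with it. For KD, a linked variant that raises Wdr41 in every cell is argued against, since the ratio in the GABAergic-like cluster had an upper bound of 1.56. In Q153R, Wdr41 was at 1.60 (1.40–1.83) in the Sim1-expressing clusters and 1.23 (0.637–2.2) in the GABAergic-like cluster. The latter interval includes both 1 and 1.60, so for Q153R the test cannot decide. Reads between Otp and Wdr41, which could show transcripts that run on, were not analysed here, and a Cre-dependent effect on Wdr41 itself stays open.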
